A study of Methylotuvimicrobium buryatense with 56 samples.

How the data were processed

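RNA-seq of *Methylotuvimicrobium buryatense* was analysed from 56 deposited tables, 1 per library, of which 36 carry the tag QC in their titles, 4 UW, 1 remake and 15 no tag (called plain here). The labels do not say what QC, UW or remake changed. RNA was extracted by an earlier published method, and a contractor prepared the libraries and sequenced them on an Illumina HiSeq, per the labels' protocols. The series mixes read lengths and paired and unpaired libraries, and a further part of the compiled data sets, published elsewhere, was not analysed here.

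Each table gives 4213 locus tags with values in transcripts per 1000000, and the deposited TPM of every library sums to 1000000. The submitters' processing notes name BWA 0.7.12-r1044, SAMtools 1.2-232 and HTSeq. The genome build, the annotation and the strand setting are not given in the sources used here, so tags that overlap or lie antisense to each other, or that share reads with a near-identical copy, are uncertain. TPM keeps no depth, so no counting interval or detection floor was computed, and a value of 0 is a listed 0. Between 47 and 147 tags were listed at 0 in a library, and 47 in every library.

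No reference genome or name table was used here and 0 tags were matched to a gene name. The 31 gene lists fixed before the data were examined, their set tests and the promoter hexamer test were therefore not run. The rule for named tags, also fixed before the data were examined, took the highest and lowest log2 fold changes among tags with an adjusted p under 0.05, a mean of at least 10 TPM over the units compared and group ranges that do not overlap, 8 in each direction. It was cut to the first 2 in each direction because tags without names say little. For the vials the rule took the highest and lowest ratios among tags of at least 50 TPM in either vial, and for the tags high in every condition those with the highest minimum. EQU24_RS12525 and the values of EQU24_RS14140 outside its own comparison are given as well, chosen after their values were seen.

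Libraries of one sample were averaged on the log2(TPM + 1) scale, which made 45 samples. Samples of one bioreactor run come from one culture, so the run was the replicate and the samples of a run were averaged. The 13 run means of 6 conditions were fitted in one model with limma 3.58.1 in R 4.3.3 (trended empirical Bayes, 7 residual degrees of freedom), which shares one estimate of spread. The slow-growth condition at high oxygen has 1 run and borrows its spread from the others. The copper samples of runs 34 and 40 were fitted as 16 samples with run as the replicate block (11 residual degrees of freedom). These samples are serial draws from 2 cultures, so their p-values measure the spread between draws and not between cultures. The block follows the labels, which number the fermentor runs. Tags with a mean of at least 5 TPM were tested, 3990 in the run means and 3960 in the copper samples, and p-values were adjusted by Benjamini-Hochberg. Fold changes are on the log2(TPM + 1) scale, which understates changes of low tags. Values with SD are means of run means or of samples in TPM.

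Values were also rescaled so that the median over tested tags was equal in all libraries. The plan was a median over protein-coding genes, which needs an annotation, so all tested tags were used. The blocks of consecutive tags (numbers 5 apart in the locus tag) were counted on the rescaled calls of at least 2-fold. Their number was compared with 100000 shuffles of the calls over the tested tags. The vials were compared as log2 ratios with no test. The copper score of a sample is its projection on the change of 130 tags that differed at least 2-fold between the start and the high-copper samples of run 34. The score is 0 at the start of each run and near 1 at the end of run 34.

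The fits were tested on simulated data with 200 changed tags among those tested and the real spread per tag. Of 100 tags changed by 2-fold, 84 were recovered in the oxygen-limited comparison of 3990 tags, 69 in the methane-limited one, 70 in methanol, 46 in high-oxygen slow growth and 49 in the nitrate one. In the copper comparisons of 3960 tags 91 of 100 were recovered at low, 98 at medium and 91 at high copper. The paired comparison of repeat libraries recovered 98 of 100, with the same change put into every pair. Alternatives were other pseudocounts, no filter on low values, rescaled values, one kind of library, other replicate units, no replicate block, each run alone and each replicate left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.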

Results

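RNA abundance was measured by RNA-seq in *Methylotuvimicrobium buryatense* 5GB1, a bacterium that uses methane or methanol as its source of carbon and energy. The 56 libraries covered 12 growth conditions, and repeat libraries of one sample reduced them to 45 samples. Of the libraries, 54 came from 15 bioreactor runs and 2 from vial cultures of the strain that the labels write as 5GB1c. Growth at the highest rate (uMax) was represented by 7 samples from 3 runs, and oxygen-limited fast growth by 6 samples from 3 runs. Methane limitation, growth on methanol, and slow growth at low oxygen with extra nitrate each had 4 samples from 2 runs. Slow growth at high oxygen had 2 samples, both from run 69. The copper conditions were serial samples of runs 34 and 40, taken before and after copper was added, with 3 samples without copper, 4 at low, 4 at medium and 5 at high copper. The series was assembled to find promoter sequences from expression under many conditions. Each library listed 4213 locus tags as transcripts per 1000000 (TPM), which hold no sequencing depth, so the counting error behind a single value was not known. The files did not pair the tags with gene names, and the tags are given here as listed, at most 2 that rose and 2 that fell in each comparison.

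One tag, EQU24_RS12525, was the most abundant in all 56 libraries. It took 40.9% to 61.2% of the TPM of the methanol libraries and 10.7% to 22.2% of that of the uMax libraries. TPM sums to a fixed total, and with this tag left out of it the median log2 fold change on methanol went from −1.05 to −0.19. In the other comparisons that median moved less, for example from −0.48 to −0.37 under methane limitation and from −0.55 to −0.61 with nitrate. Fold changes are also given relative to the median tag, after every library was brought to the same median. A block is a stretch of at least 3 consecutive tags, all at least 2-fold higher or all at least 2-fold lower than the median tag with an adjusted p under 0.05. The definition of a block was chosen after the files were seen to carry no gene names.

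**Figure D1:**
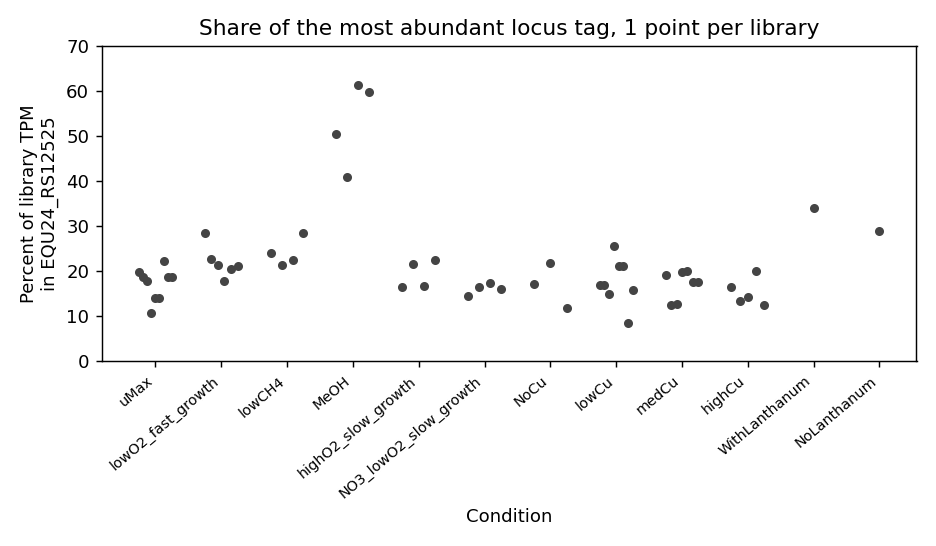
Percent of each library's TPM in EQU24_RS12525, by condition, with 1 point per library and no error bars. The 4 methanol libraries sit between 40.9% and 61.2%, above those of all other conditions.

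The effect of oxygen limitation at fast growth was asked by comparing 3 oxygen-limited runs with 3 uMax runs. No tag passed the test in this comparison. EQU24_RS14140, which is named because of the nitrate comparison, had 209, 231.9 and 1110 TPM in the 3 oxygen-limited runs and 63.8, 110 and 130 TPM in the 3 uMax runs. Limma on run means called 0 of 3990 tags at an adjusted p under 0.05, with 834 tags at an unadjusted p under 0.05 and a lowest adjusted p of 0.111. With samples in place of run means and run as a random block, 109 tags were called, 103 of them lower under oxygen limitation. These directions are those of the deposited values, and the median tag stood at −0.24 on the log2 scale in the fit of run means. Relative to the median tag, 42 tags were at least 2-fold higher and 5 at least 2-fold lower, and 0 were called. The labels describe uMax run 3 as close to oxygen-limited, and 18 tags were called without it.

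Methane limitation was compared with uMax through 2 runs against 3. EQU24_RS08705 rose from 12.95 ± 1.93 TPM (SD, n = 3 runs) to 74.5 ± 20.2 TPM (SD, n = 2 runs), a log2 fold change of 2.44 ± 0.27 (SE). EQU24_RS09450 rose from 140 ± 36.1 to 585 ± 0.039 TPM, a log2 fold change of 2.09 ± 0.22. EQU24_RS03040 fell from 449 ± 47.1 to 30.9 ± 0.53 TPM, with a log2 fold change of −3.81 ± 0.25, the lowest adjusted p of the comparison (5.08e-06) and values of 30.5 and 31.3 TPM in the 2 methane-limited runs. EQU24_RS05635 stood at 1770 ± 1040 TPM in uMax and 139 ± 6.19 TPM under methane limitation, a log2 fold change of −3.34 with an adjusted p of 0.0196. That call was not stable, with −2.84 and an adjusted p of 0.112 relative to the median tag, and an adjusted p of 0.0606 to 0.152 when run 12, 14, 20 or 21 was left out. The 2-fold changes relative to the median tag comprised 63 higher and 32 lower tags, and 16 of these 95 tags lay in 4 blocks, all higher.

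In this comparison limma called 1548 of 3990 tags, 48 higher and 1500 lower, while the median tag stood at −0.48 on the log2 scale. Against the median tag it called 347 tags, 205 higher and 142 lower. Leaving out methane-limited run 12 left 17 tags, leaving out uMax run 20 left 557 and leaving out uMax run 21 left 989.

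Growth on methanol in place of methane gave the most calls of the 5 comparisons of run means. EQU24_RS01670 rose from 14.2 ± 4.82 TPM (SD, n = 3 runs) to 125 ± 110 TPM (SD, n = 2 runs), and the adjacent EQU24_RS01665 from 13.9 ± 3.24 to 122 ± 105 TPM. Their log2 fold changes were 2.81 ± 0.58 and 2.73 ± 0.51, with adjusted p of 0.000654 and 0.000306. The 2 methanol runs had 47.4 and 203 TPM of EQU24_RS01670, against a highest uMax run of 19.5 TPM. With 1 methanol run left out, its log2 fold change was 1.77 or 3.85, and that of EQU24_RS01665 was 1.70 or 3.75. EQU24_RS03040, which also fell under methane limitation against the same uMax runs, fell to 14.8 ± 4.72 TPM on methanol (log2 fold change −4.86 ± 0.25). EQU24_RS09995 fell from 1730 ± 325 to 137 ± 78.6 TPM, within a block of 4 tags that all fell. The log2 fold changes relative to the median tag were 3.92 and 3.84 for the risen tags and −3.78 and −2.62 for the fallen ones. On that scale 222 tags were at least 2-fold higher and 318 at least 2-fold lower. Of the blocks that these formed, 28 were lower and 7 higher, and the longest held 31 consecutive tags, all lower.

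Limma called 3223 of 3990 tags on methanol, 35 higher and 3188 lower, with the median tag at −1.05 on the log2 scale. Relative to the median tag, a scale whose centring by itself evens out the directions, it called 914 higher and 893 lower, and with EQU24_RS12525 left out of the total 406 higher and 1146 lower.

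Slow growth at high oxygen was compared with uMax. EQU24_RS10665 rose from 2.45 ± 0.055 TPM (SD, n = 3 runs) to 173 TPM in the single slow-growth run, and EQU24_RS10520 from 5.45 ± 1.34 to 262 TPM. Both belonged to one block of 31 consecutive tags, all called, with log2 fold changes from 1.75 to 5.61, and the block's share of all TPM was 0.0244% in uMax and 0.338% at slow growth. EQU24_RS03040 fell from 449 ± 47.1 to 57.4 TPM, and EQU24_RS16195 from 17365 ± 6238 to 2534 TPM, with log2 fold changes of −2.94 ± 0.31 and −2.77 ± 0.41. For EQU24_RS16195 the value was −2.06 in the UW libraries only and −3.09 with the plain libraries of run 69 only. Altogether 187 of 489 tags changed by at least 2-fold relative to the median tag lay in 38 blocks, 20 of them higher and 18 lower.

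Limma called 1122 of 3990 tags here, 998 higher and 124 lower, with the median tag at 0.37 on the log2 scale, and relative to the median tag it called 519 higher and 577 lower. The slow-growth condition had 1 run, which was assumed to vary like the runs of the other groups. Run 69 had plain and UW libraries and uMax had QC and UW libraries, so library kind and condition partly changed together. Within the 2 samples of run 69, the plain and UW libraries were at least 2-fold apart in 52 and 77 tags. The libraries with the UW tag alone gave 1974 calls, but from 3 run means with 1 residual degree of freedom, so that count is not comparable.

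Low oxygen with extra nitrate was compared with high oxygen, both at slow growth. EQU24_RS14140 rose from 28.8 TPM in run 69 to 9940 ± 3436 TPM (SD, n = 2 runs), a log2 fold change of 8.34 ± 0.78 (SE) with an adjusted p of 2.19e-05. EQU24_RS17065 rose from 36.9 to 1820 ± 958 TPM, a log2 fold change of 4.82 ± 0.95, inside a block of 9 consecutive tags that rose by at least 1.69 on the log2 scale in the fit. The rise of this block was uneven, since the t4 sample of run 80 averaged 27.4 TPM per tag and the other 3 nitrate samples 449 to 836. The log2 fold change of EQU24_RS17065 was 5.92 without that sample, 5.98 without run 80 and 3.66 (adjusted p = 0.0407) without run 81. The 31-tag block was picked for being high in run 69, the only reference run here, so a lower level with nitrate was partly fixed by that choice. It averaged 109 TPM per tag in run 69 (75.6 TPM at t3 and 142.7 TPM at t4), 11.7 TPM with nitrate and 7.86 TPM in uMax. Within it, EQU24_RS10535 fell from 167 to 6.32 ± 1.76 TPM and EQU24_RS10665 from 173 to 7.33 ± 2.70 TPM. Relative to the median tag, 106 tags were at least 2-fold higher and 88 lower, and 89 of these 194 lay in 17 blocks.

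In the nitrate comparison limma called 904 of 3990 tags, 83 higher and 821 lower, with the median tag at −0.55 on the log2 scale, and relative to the median tag 274 tags, 151 higher and 123 lower. The oxygen supply and the nitrate differed together between these groups, and leaving out nitrate run 81 left 170 calls and leaving out run 80 left 519.

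The response to copper was followed in 2 cultures. In both, the copper level in the labels rose with the time since the start. No culture was followed over the same times without added copper. The effects of copper level and of elapsed time therefore cannot be told apart. In run 40, EQU24_RS05885 had 16751 and 17912 TPM in the 2 samples at the start, 18662 at 10 min, 18343 at 20 min, 11341 at 40 min, 4748 at 60 min, 946 at 90 min and 89.9 TPM at 180 min. The sample labelled 150 min broke this order, with 7268 TPM. In run 34 the tag went from 24734 TPM at the start to 96.9 TPM at 3 h and 40.4 TPM at 8 h. EQU24_RS19310 rose, though not steadily, from 5485 and 4676 TPM at the start of run 40 to 14273 TPM at 40 min, 24039 at 60 min, 18992 at 90 min, 14004 at 150 min and 24978 TPM at 180 min, and from 5249 TPM to 27577 TPM at 3 h in run 34. The 2 libraries of the 60 min sample had 17823 and 30256 TPM of it.

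**Figure D2:**
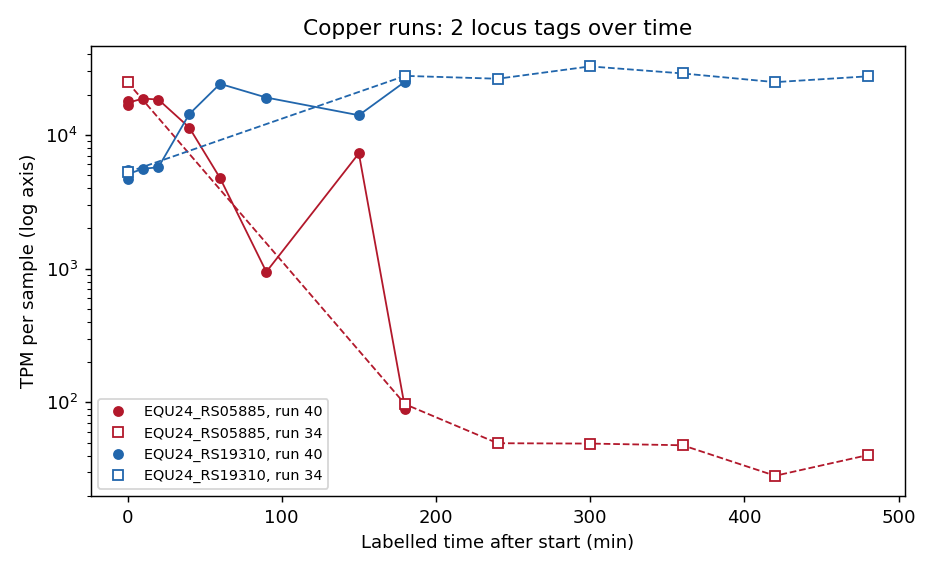
TPM of EQU24_RS05885 (red) and EQU24_RS19310 (blue) on a log axis against the labelled time in minutes, with 1 point per sample, filled circles for run 40 and open squares for run 34. The lines join means of samples with the same time, and the fall of EQU24_RS05885 from 16751 and 17912 TPM to 89.9 TPM at 180 min is interrupted by 7268 TPM at 150 min.

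Low copper (10 to 60 min) gave no called tag as a group, although its samples were not alike. Relative to the median tag and the start of the run, 3 tags were at least 2-fold higher and 0 lower at 10 min and again at 20 min, 12 and 9 at 40 min, and 81 and 41 at 60 min. The 60 min counts are uncertain, because the 2 libraries averaged there differed by at least 2-fold in 96 tags, against 0 at 10 and 40 min and 49 at 20 min. For the 4 samples as a group, limma with run as a block called 0 of 3960 tags. At an unadjusted p under 0.05 there were 295 tags, and the lowest adjusted p was 0.6254. In simulated data 91 of 100 tags changed by 2-fold were recovered, but there every low-copper sample carried the same change. That share does not cover a change that began only at 40 or 60 min, so the 0 calls do not speak against one.

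Medium copper (90 to 180 min in run 40 and 3 h in run 34) gave 939 called tags of 3960, 183 higher and 756 lower. With QC libraries only, which also left out the second start sample of run 40, there were 198, 76 higher and 122 lower. EQU24_RS05885 fell from 19799 ± 4313 TPM (SD, n = 3 samples) to 2100 ± 3468 TPM (SD, n = 4 samples), a log2 fold change of −5.41 ± 0.98 with an adjusted p of 0.00290. EQU24_RS05895 fell by 5.34 ± 0.95 on the log2 scale, and both lay in a block of 13 consecutive tags whose share of all TPM was 7.18% without copper and 0.761% at medium copper. That share rested mainly on the sample labelled 150 min, in which these tags and 1 neighbour averaged 1872 TPM per tag, against 37.3, 39.0 and 232.9 TPM in the others. The log2 fold change of EQU24_RS05885 was −6.58 without it, −4.48 without 180 min and −4.34 in run 40 alone, where this tag (adjusted p = 0.0592) and the other 3 named here lost their calls. EQU24_RS19310 rose from 5137 ± 416 to 21388 ± 6095 TPM and its neighbour EQU24_RS19305 from 6095 ± 832 to 22015 ± 5226 TPM, with log2 fold changes of 2.04 ± 0.39 and 1.84 ± 0.35. Relative to the median tag the calls were 671 higher and 249 lower, and 356 tags were called from run 40 alone. Leaving out 1 sample gave 388 calls (without the second start sample of run 40) to 1188 (without the sample labelled 150 min), with 474 without 180 min, 542 without 90 min, and 571 without either sample of run 34.

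High copper (4 to 8 h) was sampled in run 34 alone. EQU24_RS05885 stood at 43.1 ± 9.06 TPM (SD, n = 5 samples), a log2 fold change of −7.88 ± 1.17 from no copper with an adjusted p of 0.000471, and EQU24_RS05890 at 33.7 ± 5.12 TPM, a log2 fold change of −7.52 ± 1.16. The fold change of EQU24_RS05885 varied with the samples and the replicate block. It was −9.16 in run 34 alone, −8.82 without that block and −5.52 without the start sample of run 34. The replicate block sets the same run difference in every condition and takes it partly from medium copper. There EQU24_RS05885 had 96.9 TPM in run 34 and 946, 7268 and 89.9 TPM in run 40. At the start run 34 was the higher one, with 24734 against 16751 and 17912 TPM. The high-copper fold changes of this fit are therefore not those within run 34 alone. The block of consecutive tags with EQU24_RS05885 and EQU24_RS05890, now of 14 tags, took 0.0384% of all TPM. EQU24_RS19310 reached 27913 ± 2932 TPM and EQU24_RS19305 reached 27206 ± 2775 TPM, with log2 fold changes of 2.23 ± 0.46 and 2.10 ± 0.42. Limma called 288 of 3960 tags, 155 higher and 133 lower, and relative to the median tag 377 higher and 207 lower. The 31-tag block of high-oxygen slow growth was lower, with 31 tags called at medium copper and 30 at high copper as deposited. It averaged 73.7 TPM per tag without copper, 11.1 TPM at high copper and 7.86 TPM in uMax. Of 117 tags changed at least 2-fold relative to the median tag, 94 were lower, and 73 of these lay in 7 blocks. Without a replicate block the count was 689, and without the single start sample of run 34 it was 19, at which the named tags were no longer called.

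The 2 cultures were set beside each other at matched times, run 40 at 180 min and run 34 at 3 h, each against its own start. Relative to the median tag, 74 tags were at least 2-fold lower in run 40, and 73 of them were also lower in run 34. The sets of tags at least 2-fold lower shared 54 tags, where independent sets of 74 and 83 of 3960 tags would share 1.55. Of the 113 tags at least 2-fold higher in run 40, 112 were higher in run 34, but 25 were at least 2-fold higher there, out of 48, where independent sets would share 1.37. The fold changes of the 2 cultures correlated across tags with r = 0.85, and tags are not independent replicates. At the matched times EQU24_RS05885 had 89.9 TPM in run 40 and 96.9 TPM in run 34. Over all medium-copper samples its fold change was −7.98 in run 34, from 3 h alone, and −4.34 in run 40. The latter averages 90, 150 and 180 min, with 946, 7268 and 89.9 TPM, so this difference between the runs mixes times. A limma test of such differences called 0 tags, but run 34 had 1 sample on each side, so that result is no sign that the runs agreed.

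The effect of lanthanum was seen in 1 vial with and 1 vial without the metal, so the difference has no replicate check. EQU24_RS18130 had 5462 TPM without lanthanum and 1.06 TPM with it, and EQU24_RS18135 had 3864 and 0.593 TPM. They belonged to 14 consecutive tags that held the 14 lowest ratios of the 1903 tags with at least 50 TPM in either vial. Together these 14 took 3.69% of all TPM without lanthanum and 0.00728% with it. In the other direction EQU24_RS18605 had 3400 TPM with lanthanum and 379 TPM without, and EQU24_RS19210 had 113 and 25.4 TPM. Of the 1903 tags, 97.6% were within 2-fold, 15 were at least 4-fold lower with lanthanum, and 2 at least 4-fold higher. Between 16 pairs of bioreactor samples of one run and condition, the number of tags at least 4-fold apart was 0 at the median and 45 at the highest. The samples of such a pair share a culture and the 2 vials do not, so this range leaves out variation between cultures.

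**Figure D3:**
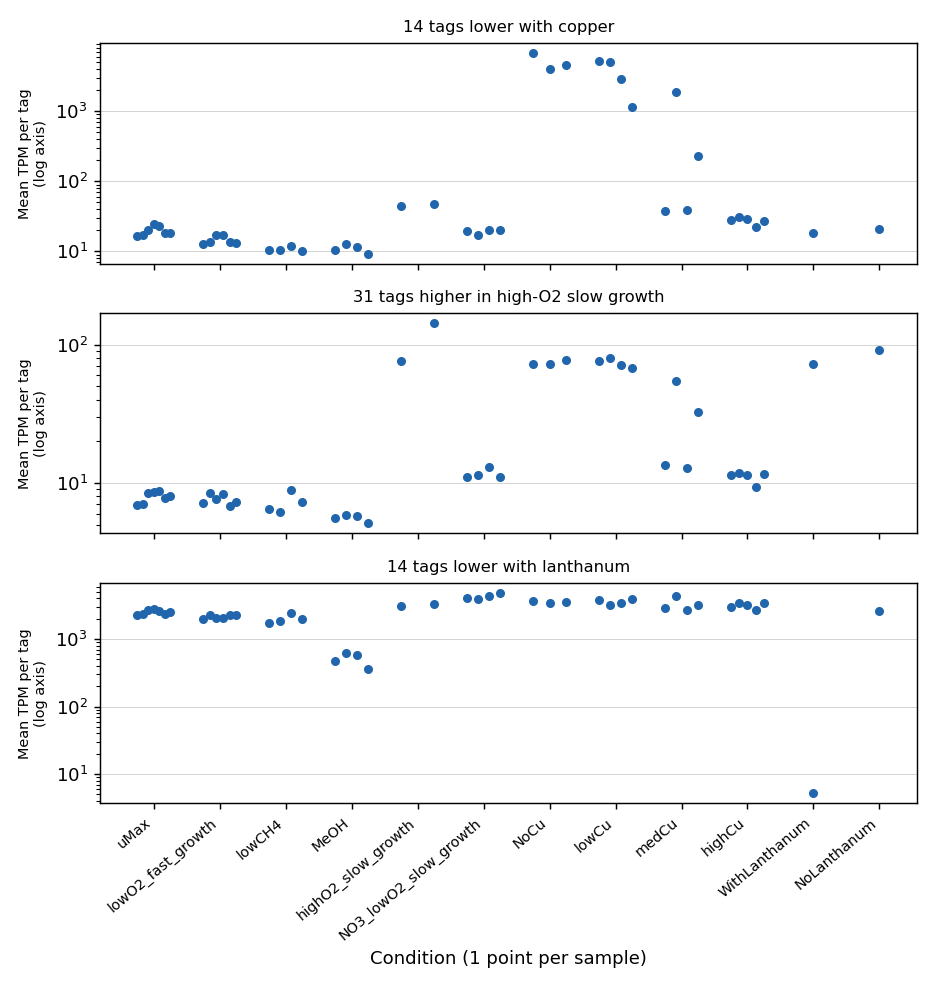
Mean TPM per tag, on log axes, of 3 blocks of consecutive tags in each sample, by condition and with 1 point per sample. The 14 copper tags are high without copper, the 31 tags of high-oxygen slow growth are also high without copper and in both vials, and the 14 lanthanum tags average 5.20 TPM with lanthanum and 2639 TPM without.

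Tags whose RNA abundance stayed high across conditions were counted, as the series was assembled to find promoter sequences from expression. The plan was to count protein-coding genes only, which needs an annotation. All tags were used instead, so tags of non-coding RNA could be among those counted. The top 3% of tags (126) were taken in each of the 12 conditions, and 36 tags were in the top 3% of every one. EQU24_RS12525 had the highest minimum, from 153362 TPM at high copper to 553083 TPM on methanol. EQU24_RS19765 was next, from 27075 TPM in high-oxygen slow growth to 176897 TPM on methanol. The 36 tags took 35.1% of all TPM without copper and 80.6% on methanol. They were not constant in level, since 1 of the 36 stayed within 2-fold and 9 within 4-fold over the 12 conditions. In every single library, 29 tags were in the top 3%.

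Repeat libraries of one sample were compared to show how far they differed. In the 6 samples of run 40 with a QC and a plain library, limma on the paired differences called 0 of 3951 tags. There were 277 tags at an unadjusted p under 0.05, and the lowest adjusted p was 0.503. The test looks for a difference shared by the 6 pairs, so the 0 calls do not speak against one in only some of them. The SD of the log2 difference between the libraries of one sample was 0.123 to 0.181 in 7 of 11 samples. In the samples labelled 20 and 60 min it was 0.326 and 0.400, and in the 2 samples of run 69 it was 0.376 and 0.407.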

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

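All tests of explanations in this part were chosen after the results were seen. In groups of 4 to 10 samples, 31 sets of values were checked for a sample far from the others, and 5 had one, where chance gives about 1 in 20. At medium copper the sample labelled 150 min had 7268 TPM of EQU24_RS05885 (others 89.9 to 946), 4968 TPM of EQU24_RS05890 (others 65.3 to 499) and 4772 TPM of EQU24_RS05895 (others 69.1 to 571), which are neighbours in one block and so not separate signs. At high copper the 5 h sample had 32125 TPM of EQU24_RS19305 (others 25419 to 26398). The 7 h sample had 29.8 TPM of EQU24_RS05895 (others 41.3 to 43.9).

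The sample labelled 150 min lay out of time order over the whole copper response, with a copper score of 0.127 between those of 40 min (0.067) and 60 min (0.178), and far under 90 min (0.357) and 180 min (0.617). One failed library is argued against, since the 2 libraries of the 150 min sample differed with an SD of 0.123 on the log2 scale. That is less than every other repeat pair of run 40. A swap with another sample of run 40 needs a partner out of place, and 0 of the other samples from 40 to 180 min were. A time label that is too late stays open, since the nearest other sample over all tested tags was that of 40 min, with an SD of 0.242. The next were 10 min (0.296), 90 min (0.308) and 60 min (0.311), so these distances do not place the sample between 40 and 60 min. A passing reversal of the response in the culture cannot be told apart from a late label. Only 1 culture was sampled then, with 7268 TPM of EQU24_RS05885.

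On methanol, 3188 of 3223 called tags were lower, with the median tag at −1.05 on the log2 scale. With the most abundant tag left out of the total the median rose to −0.19, so a large part of the shift is consistent with the share taken by EQU24_RS12525. The kind of library hardly differed, since all methanol libraries were QC and every uMax sample had a QC library. QC libraries alone gave 3179 calls. From these groups that setting left out only the UW repeats of uMax, so a near-equal count was largely fixed by the design. Whether most transcripts also fell per cell cannot be told apart from this, because TPM has no standard of amount per cell. Why the share rose on methanol was not tested.

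In 4 of 11 samples the repeat libraries differed more than elsewhere, those of 20 and 60 min of run 40 and both of run 69. Sampling noise of low tags is argued against, since among tags of at least 200 TPM the SD of the log2 difference was at least 0.359 in these 4 pairs and at most 0.0760 in the other 7. A library batch within each run stays open as a candidate explanation, since the differences correlated across tags with r = 0.69 between 20 and 60 min and r = 0.75 between the samples of run 69, and with r of 0.02 to 0.12 among the other 4 samples of run 40 with QC and plain libraries. An exchange of a 60 min library with one of 40 or 90 min is argued against. The 2 libraries of 60 min differed by 0.0147 in copper score, against 0.111 to the nearer of those times. The sample labelled 150 min was closer in score, at 0.127 against 0.178 at 60 min. Over all tags its remake library was nearer to the plain 60 min library than the QC partner was, with SD of 0.289 and 0.400. An exchange with that sample was not tested. In the other 3 pairs a library of another sample was nearer than the partner by over 1.5 times, in 3 of 3, which a shared batch also gives, so a wrong label cannot be told apart there. No biological explanation was tested.

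Other splits of the same samples were counted, in the copper comparisons with samples exchanged within a run only. At medium copper the real split called 939 tags and was the 1 of 20 splits with as many, and the highest other called 883. That other split puts the sample labelled 150 min with the copper-free samples, and so points to that sample's place. At high copper the real split called 288 tags, 1 of 6 splits with as many, and the highest other called 0. These splits are too few for a share under 0.05. The same holds for the 15 splits at low copper and the 10 of oxygen limitation, where the real count was 0 and the highest others called 8 and 0. A real count of 0 is reached by every split, 15 of 15 and 10 of 10 there and 32 of 32 sign flips of the QC and plain pairs (highest other 0), so these counts say nothing about chance.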

How the results depend on the processing

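The alternatives that left the most abundant tag out, counted blocks from 2 tags, dropped single libraries of 20 and 60 min or of run 69 or the t4 sample of run 80, or used deposited values in the matched-time copper comparison were chosen after seeing the data. Of 136 alternative counts, 105 stayed within 1.5 times of the reported count. None of the 320 values of named tags with a test reversed, and 307 kept their call. The 13 lost calls were those of EQU24_RS05635, the 4 tags named at medium copper in run 40 alone and the 4 named at high copper without the start sample of run 34. Rescaling to the median tag gave 347 calls under methane limitation, 1807 on methanol, 274 with nitrate and 584 at high copper. Leaving out the most abundant tag gave 1552 on methanol and 1446 with nitrate. For oxygen limitation, pseudocount 10 gave 2 calls and run as a random block 109. UW libraries only gave 1974 calls at high-oxygen slow growth, from 3 run means with 1 residual degree of freedom, so not comparable. Medium copper had 198 calls in QC libraries only, 356 in run 40 alone and 95 in run 34 alone, all from fewer samples. The QC setting also left out the second start sample of run 40, and leaving out only that sample gave 388 calls. The 198 therefore does not separate library kind from the loss of that sample. Run 34 alone had 1 sample on each side, so its 95 calls are not comparable. For the replicate block, the fit without it gave 689 calls at high copper, 750 at medium and 0 at low copper, and no named tag lost its call in it. The causes were not tested. Leaving out each replicate gave 0 to 18 calls for oxygen limitation (18 without uMax run 3), 17 to 1943 for methane limitation, 2841 to 3312 for methanol, 823 to 1139 for high-oxygen slow growth and 170 to 519 with nitrate, the lone run then assumed to vary like the other groups. It gave 0 at low copper, 388 to 1188 at medium copper, 19 to 382 at high copper and 0 for the QC and plain pairs. Blocks counted from 2 tags held 50 tags under methane limitation, 261 on methanol and 293 at high-oxygen slow growth. The tags high in every condition numbered 13 for the top 1%, 81 for the top 5% and 56 in the 10 bioreactor conditions. The lanthanum count of 17 tags was 15 with pseudocount 10. The gene lists, their set tests with preset and estimated correlation or fry, and the hexamer test with its alternatives were not run, since no names or genome were used here. Depth is unknown, so what it limits could not be stated.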

Other observations

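The observations in this part were chosen after the data were seen. The 9-tag block around EQU24_RS17065 that rose with low oxygen and nitrate averaged 449 to 836 TPM per tag in 3 of the 4 samples there and 27.4 TPM in the t4 sample of run 80. It averaged 15.9 and 17.1 TPM in high-oxygen slow growth and 4.56 to 9.43 TPM in uMax. In oxygen-limited fast growth, run 19 had 26.5 and 28.8 TPM, and runs 11 and 22 had 6.14 to 10.7 TPM. No tag of this block was called in the oxygen-limited comparison, where its median log2 fold change was 0.90. EQU24_RS14140 had 3348 and 3738 TPM in the vials. The nitrate comparison and the oxygen-limited comparison share no library. Relative to the median tag, 42 tags were at least 2-fold higher in oxygen-limited growth and 178 in the nitrate comparison, and 25 were in both, where independent sets among 3990 tags would share 1.87. Of the tags at least 2-fold lower, 5 and 114, none was in both, and 1 tag moved in opposite directions. The fold changes correlated across tags with r = 0.31, and tags are not independent.

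The 14 tags that were low with lanthanum averaged 2463 TPM per tag in uMax and 4278 TPM in the nitrate condition. On methanol they averaged 459 TPM, with 14 called lower as deposited and 10 relative to the median tag. Of all 3990 tested tags, 3188 were called lower on methanol as deposited and 893 relative to the median tag. The 31-tag block of high-oxygen slow growth averaged 109 TPM per tag in that condition, with 75.6 TPM at t3 and 142.7 TPM at t4. It averaged 73.7 TPM without copper, 73.4 TPM at low copper, and 72.8 and 91.4 TPM in the vials with and without lanthanum. In oxygen-limited growth, methane limitation and methanol it averaged 7.61, 7.199 and 5.43 TPM. What these conditions have in common beyond their labels was not tested.

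Consecutive locus tags moved together. Over the means of the 10 bioreactor conditions the median correlation of 3699 pairs of neighbouring tags was 0.88, and that of 99977 random pairs was 0.63. The tags in blocks numbered 60 of 92 at medium copper and 79 of 117 at high copper, and the highest number in 100000 shuffles was 6 and 7. The share was lower elsewhere, with 16 of 95 under methane limitation and 165 of 540 on methanol (highest in shuffles 6 and 31). It was 187 of 489 at high-oxygen slow growth and 89 of 194 with nitrate (highest in shuffles 27 and 12). On methanol, 18 of the 126 tags in the top 3% were in the top 3% of no other condition, and in high-oxygen slow growth 13 were.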
